A study of Danio rerio with 80 samples.

How the data were processed

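Whole brains of 80 adult zebrafish were sequenced one by one, 8 females and 8 males in each of 5 conditions. Per the labels' protocols, 2 µg of total RNA per fish was selected with poly-T beads, made into a library with the NEBNext Ultra RNA kit and read as 150 bp pairs on a HiSeq machine, with 20 Mreads (1 Mread is 1000000 reads) planned per sample. The submitters' processing notes name Trim Galore 0.4.5, STAR 2.5.4b, DESeq2 without a version, R 3.5.0 and the genome build GRCz11, without saying what each did. How reads were counted, with which annotation, whether by strand, and how the libraries were scaled is not stated. The kit is not described as marking the strand, and how reads shared between overlapping or similar genes were assigned is not known and was not tested.

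The deposited values are log2 normalized expression, 1 value per gene and fish, per the file headers. Within each library every value under 5000 reads lay within 0.02 of a whole number of reads times the worth of 1 read (100% of values), so the reads behind them could be recovered. A count of 0 stood in the deposited log2 values as 0.9 read. The linear values of a library summed to between 1.27 and 1.42 times 1000000. A value is thus reads divided by a library factor that is smaller than the Mreads recovered for the listed genes. How this factor was set is not known, and levels are written here as reads per Mread (RPM) for short. No gene length correction was seen. The recovered reads came to 9.01 to 20.3 Mreads per library, and a gene at 10 RPM had 71.2 to 144 reads behind it.

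The table listed 23473 entries for 22925 gene identifiers, and 404 identifiers stood on several lines, 18 of them among the tested genes, which were kept apart by their start position. Gene symbols and coordinates were taken as deposited. Of the identifiers 22752 were found in the gene name table supplied with the data and 173 were not, and 17 symbols had been turned into dates and could not be searched by name. No genome sequence was used here. Genes were tested where their mean over all 80 libraries was at least 10 RPM, which kept 10231.

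Differences were tested with limma 3.58.1 in R 4.3.3: a linear model of the log2 values with 1 mean for each of the 10 groups, a moderated test with a mean-variance trend, two-sided, and Benjamini-Hochberg adjustment over all tested genes with a threshold of 0.05. A comparison over both sexes is the mean of the female and the male difference. The comparisons were each exposure against control over both sexes and in each sex, the interaction of exposure with sex, the mixture against PFOS at each level, the high against the low level of each, females against males in control fish and over all groups, and an F test of any exposure. Fish were the replicates. The 4 fish of 1 exposure replicate come from 1 exposure, so p-values over fish measure the spread between fish.

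The replicate numbers were taken to pair the samples, because the labels give each number 1 age in every condition. As a check, the mean deviations of same-numbered exposure replicates from their group means correlated with a median of 0.369 over 40 pairs, from -0.185 to 0.825, against -0.148 between other numbers. Of the 40 pairs 36 were over 0.1, and without the PFOS70 fish of number 5 the lowest was 0.17. Of the 20 exposure replicates 18 correlated best with their own number. The fit with the number as a block was an alternative fixed before the data were examined, and its value stands beside a result where it changed the call.

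The 30 gene lists, the panel of 30 genes, the rule for named genes, the tests and most of the alternatives were fixed before the data were examined. The named genes are those past the threshold with the same direction in both sexes, up to 12 each way in an exposure over both sexes and between the sexes, and up to 5 each way in the other comparisons. Where under 10 passed, the genes with the smallest unadjusted p follow, as values that did not pass, as do up to 4 members of each list that passed. Names of clone type are counted, and named only where the text says so. The rule covered the sexes in control fish and was extended to all groups after the counts were seen. Lists were tested with limma's camera with the preset correlation of 0.01, again with an estimated correlation (median 0.197 over the lists, from -0.00317 to 0.797), and with fry. Of the 30 lists 26 had at least 5 tested members. The 4 others were pituitary hormones with 0 members, lymphocytes and neutrophils with 3, retina and pineal with 3, and skin, bone and cartilage with 4; the median level of their listed genes was between 0.3 and 1.04 RPM. Exact permutation tests used the means of 4 fish per exposure replicate, and the 4 exposures of each measure were adjusted together. They ignore the pairing by number, so an exact test of the paired differences within numbers stands beside those against control.

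The alternatives were no filter and a filter at 100 RPM (2751 genes), quantile normalization, the variance model without trend and robust, library weights, the replicate block, the correlation between fish of 1 exposure replicate, replicate means, fits of 2 conditions alone, leaving out each number, and voom on the recovered reads. Added after seeing the data were median-of-ratios scaling, the block together with the correlation, the composition component or the clock component as a covariate, fits without the 4 PFOS70 fish of number 5 and fits without 3 males of number 3. The clock component is the first principal component of the 34 clock genes and held 57.3% of their variance.

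The pipeline was tested on simulated reads for POP70 against control with 10231 genes, of which 200 were changed. At the smallest fold simulated, 0.32 on the log2 scale, it recovered 26 of 50 changed genes (52%). At a fold of 1.5 it recovered 84% of the changed genes, at 2 96% and at 3 96%, and it called 8 of the 10031 unchanged genes. Each simulated gene and fish was drawn independently, without the correlation of 0.236 between fish of 1 exposure replicate. The simulation had no difference between numbers and no composition component either, so these shares do not carry over to the real fish. Permutation tests were run in R, and figures were drawn in python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.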

Results

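Gene expression was measured by poly-A RNA sequencing in single whole brains of adult zebrafish of the AB strain. As embryos and larvae, from 6 to 96 hours after fertilisation, the fish had been kept in a mixture of persistent organic pollutants (POP), in perfluorooctane sulfonic acid (PFOS) alone, or in the solvent, 0.1% dimethyl sulfoxide, which served as control. POPs are long-lived chemicals that build up in tissue, and PFOS is a fluorinated surfactant among them. The mixture was given at 10 times (POP10) and 70 times (POP70) the levels in human blood that it was modelled on, and PFOS alone at the amounts that these mixtures contained, 0.3 mg/L (PFOS10) and 2.06 mg/L (PFOS70). The fish then grew up in clean water and were sampled at 219 to 240 days, so each comparison with control asks whether an early exposure left a difference in the adult brain. Each of the 5 conditions had 4 exposure replicates, numbered 3 to 6, and each replicate gave 2 females and 2 males. This makes 10 groups of 8 fish and 80 libraries. The age went with the number: fish of number 3 were 240 days old, of number 4 233 days, of number 5 226 days and of number 6 219 days.

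The reads recovered from the deposited values came to between 9.01 and 20.3 Mreads (1 Mread is 1000000 reads) per library, with a median of 12.1 Mreads. The mean per condition was 12.5 Mreads ± 1.79 (SD, n = 16) in control fish, 12.7 ± 2.14 in POP10, 12.6 ± 2.62 in POP70, 12.3 ± 1.57 in PFOS10 and 13.8 ± 2.46 in PFOS70. A gene at 10 reads per Mread (RPM) on the deposited scale, the lowest mean that was tested, had 71.2 reads in the smallest library and 144 in the largest. The divisor of this scale is smaller than the recovered Mreads, and how it was set is not known. No 2 libraries agreed within sampling noise. Mitochondrial transcripts took 7.2% to 18.2% of the reads. The first principal component of the 10231 tested genes held 40.7% of the variance. Over the 80 libraries it went with the mean of the GABA and glutamate genes (Pearson's r = 0.977, Spearman's rho = 0.973) and against that of the ribosomal protein genes (r = -0.736, rho = -0.744). Each of these had a permutation p of 1e-05, the smallest that 100000 permutations can give, and an adjusted p for r of 2.89e-05 over 26 lists. Within the 4 numbers r lay between 0.924 and 0.987 for the first list and between -0.888 and -0.612 for the second. Without the 2 libraries farthest from the median of the component r was 0.975 and -0.754. Other lists went with it too, such as the genes of mature neurons (r = 0.954, rho = 0.958) and of the circadian clock (rho = 0.598), each with the same permutation p and adjusted p. The component was computed from genes that include these lists, so part of each r is built in. The permutation p therefore does not show that a list is particular to the component. The exposure replicate number took 0.335 of the variance of this component and the condition 0.0648. The component is taken here as a measure of the RNA composition of a library and is called the composition component. What sets it was not tested. It averaged -0.34 ± 0.86 (SD, n = 16) in control fish, -0.03 ± 0.80 in POP10, -0.17 ± 0.84 in POP70, 0.39 ± 1.07 in PFOS10 and 0.15 ± 1.29 in PFOS70.

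A pair of immediate-early genes rose in the brains of POP10 fish. Immediate-early genes are the transcripts that neurons make within minutes of being activated. The gene egr1, which encodes a zinc finger transcription factor, rose by 0.70 ± 0.12 on the log2 scale (SE), from 8.84 ± 0.38 in control fish (SD, n = 16) to 9.55 ± 0.41 in POP10 fish (n = 16). This is a 1.63-fold difference, with an adjusted p of 0.00202 (limma). The gene ier2a, an immediate-early response factor, rose by 1.16 ± 0.22, 2.23-fold, from 4.14 ± 0.75 to 5.29 ± 0.86, with an adjusted p of 0.0093. Both genes were higher in POP10 than in control in 4 of 4 numbers. The ier2a difference was largest in number 5, from 3.547 in control to 6.172 in POP10, and smallest in number 6, from 4.245 to 4.722. Over the alternatives the difference lay between 0.665 and 1.381 for ier2a and between 0.536 and 0.808 for egr1. On the GRCz11 assembly egr1 (ENSDARG00000037421) lies on chromosome 14 from 21332522 to 21336385, and ier2a (ENSDARG00000099195) on chromosome 3 from 33761549 to 33762726.

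Of the 31 immediate-early genes tested, 26 had a higher mean in POP10 and the median difference was 0.19. The list rose by camera with its preset correlation (adjusted p = 9.92e-13), and 10 members passed when adjusted over the list alone, against 2 over all genes. With an estimated correlation the list had an adjusted p of 0.24. Members that did not pass over all genes were npas4a, an activity-regulated transcription factor of neurons, at 1.33 ± 0.33, egr4 at 1.12 ± 0.25, and fosab, a component of the AP-1 factor, at 1.08 ± 0.30. Over the alternatives they lay between 0.813 and 1.605, 0.643 and 1.331, and 0.514 and 1.383, in this order. The npas4a difference was largest in number 5, from 5.953 in control to 8.848 in POP10. The 79 ribosomal protein genes fell by the preset camera test (adjusted p = 1.15e-05), with 70 lower and a median of -0.06; adjusted p = 0.974 with an estimated correlation. With the composition component as a covariate, a fit added after seeing the data, 52 were lower and the median was -0.02. In the same direction, these genes took 3.88% ± 0.47 of the reads in POP10 fish and 4.08% ± 0.56 in control fish (SD, n = 16).

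Limma called 2 of 10231 genes in POP10, both higher, and 405 had an unadjusted p under 0.05, where 512 are expected by chance. Among the other genes with the smallest p, none of which passed, biotinidase (btd) stood at 0.41 ± 0.10 and ccdc93 at -0.26 ± 0.07. With the exposure replicate number as a block egr4 passed besides these 2 genes. With the mean of 4 fish as the unit, egr1 had an exact two-sided permutation p of 0.0571 (n = 4) and ier2a of 0.0857, and the smallest p that 4 against 4 can give is 0.0286. Paired by number, the exact permutation p was 0.125 for both genes, the smallest that 4 pairs can give. Fish of 1 exposure replicate are not independent exposures: with a correlation of 0.236 between them in the model limma called 0 genes. It also called 0 without number 5 and with control and POP10 fish alone in the fit, 5 without number 3, 7 with library weights and 1 with voom on the recovered reads.

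In POP70 fish the immediate-early genes rose as a list. Of the 31 genes, 26 had a higher mean than in control and the median difference was 0.26. The list passed camera with the preset correlation (adjusted p = 1.22e-27) and with an estimated one (adjusted p = 0.00454). It did not pass fry (adjusted p = 0.0644, and 0.628 for changes in either direction) except with the number as a block (0.0231). Fry called 0 of 26 lists in each of the 4 exposures without the block and, with it, 1 in POP70 and 2 in PFOS10. In this list 13 members passed when adjusted over the list alone, against 0 over all genes. The leading members were nr4a1, an orphan nuclear receptor induced by activity, at 1.68 ± 0.35, from 2.45 ± 0.89 to 4.13 ± 1.32 (SD, n = 16), and npas4a at 1.43 ± 0.33. The mean of ier2a was 0.97 ± 0.22 above control, that of the kinase gene sik1 0.66 ± 0.15, and that of egr1 0.56 ± 0.12. Each of these missed the threshold over all genes with an adjusted p between 0.102 and 0.11.

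With the exposure replicate number as a block, limma called 8 genes in POP70, all higher. They were ier2a, sik1, egr1, npas4a, egr2a, nr4a1, the adhesion receptor gene adgrb1b and the uncharacterised zgc:122979, a name chosen after its values were seen. Without the block limma called 0 genes, and 159 had an unadjusted p under 0.05. With the correlation between fish of 1 exposure replicate in the model the count was 0 as well. It was 1 without number 3, 2 without number 4 and 4 under the stricter filter, which left 2751 genes. With block and correlation together limma called 2 genes, where the block alone gave 8.

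Other lists passed in POP70 by the preset test alone. This test called 6 lists in all, and with whole exposure replicates exchanged between POP70 and control the other splits gave a median of 6. The erythrocyte genes rose, with 13 of 15 higher and a median of 0.22 (adjusted p = 0.000336; adjusted p = 0.655 with an estimated correlation). Their members included nt5c2l1 at 0.74 ± 0.28 and alas2, the first enzyme of haem synthesis in red cells, at 0.41 ± 0.26. The appetite and energy peptides rose, 17 of 19 higher with a median of 0.14 (adjusted p = 0.00194; 0.655 as the adjusted p with an estimated correlation), among them tac1, the tachykinin precursor, at 0.23 ± 0.14. The thyroid axis rose, 7 of 9 higher with a median of 0.09 (adjusted p = 0.0447; 0.223 as the adjusted p with an estimated correlation). Its members included slc16a10, a thyroid hormone transporter, at 0.33 ± 0.13. The myelin genes fell, 15 of 18 lower with a median of -0.08 (adjusted p = 0.0485; 0.83 as the adjusted p with an estimated correlation), plp1a among them at -0.23 ± 0.16. The ribosomal protein genes fell, 78 of 79 lower with a median of -0.10 (adjusted p = 1.59e-22; 0.655 as the adjusted p with an estimated correlation; median -0.08 with the composition component as a covariate). No member of these 5 lists passed when adjusted over the list alone.

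In PFOS10 fish ier2a rose by 1.16 ± 0.22, 2.23-fold, from 4.14 ± 0.75 to 5.30 ± 0.31 (SD, n = 16), with an adjusted p of 0.0176 (limma). All 4 exposure replicates of PFOS10 had a higher ier2a mean than all 4 of control. Their exact two-sided permutation p was 0.0286 (n = 4), the smallest that 4 against 4 can give, and it became 0.114 after adjustment over the 4 exposures. Paired by number, the exact permutation p was 0.125, the smallest that 4 pairs can give. Of the 31 immediate-early genes 27 had a higher mean than in control, with a median of 0.30. The list rose by camera with the preset correlation (adjusted p = 1.73e-07; adjusted p = 0.628 with an estimated correlation), and 12 members passed when adjusted over the list alone, against 1 over all genes. Members below the threshold over all genes were npas4a at 1.44 ± 0.33, nr4a1 at 1.34 ± 0.35 and egr3 at 0.64 ± 0.17.

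The ribosomal protein genes fell in PFOS10 by the preset test, 78 of 79 lower with a median of -0.19 (adjusted p = 8.34e-47; adjusted p = 0.287 with an estimated correlation). When adjusted over the list alone 47 passed, all lower, and over all genes 0 did. With the mean of 4 fish as the unit, the list mean had an exact two-sided permutation p of 0.171 (n = 4). Adjusted over the 4 exposures it was 0.343, so at this level the fall did not pass. Paired by number, the exact permutation p was 0.125, the smallest that 4 pairs can give. The members with the smallest p were rps26 at -0.32 ± 0.08, rpl31 at -0.20 ± 0.06 and rplp1 at -0.40 ± 0.13. These genes took 3.54% ± 0.58 of the reads in PFOS10 fish and 4.08% ± 0.56 in control fish (SD, n = 16), and PFOS10 fish had the highest mean of the composition component of the 5 conditions. With this component as a covariate, a fit added after seeing the data, the list median was -0.08 in PFOS10 and -0.10 in PFOS70, and with a component computed without these genes 49.1% of their mean was left. The 13 transcripts encoded in the mitochondrial genome fell, 11 of them lower with a median of -0.09 (adjusted p = 0.0193; adjusted p = 1 with an estimated correlation), mt-nd6 among them at -0.26 ± 0.14.

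Limma called 1 gene in PFOS10 and 1079 had an unadjusted p under 0.05. With the number as a block it called 6, all higher: ier2a, egr1, npas4a, zgc:122979, the exoribonuclease gene dis3l2 at 0.42 ± 0.11 and the splicing helicase gene dhx38 at 0.27 ± 0.07 (SE without the block). With the correlation between fish of 1 exposure replicate it called 0. It also called 0 after quantile normalization, under the stricter filter, with voom and without number 4, 5 or 6 in turn, and it called 6 without number 3, 6 with library weights and 2 with control and PFOS10 fish alone in the fit.

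In PFOS70 fish the immediate-early genes had means near those of control fish. The gene ier2a differed from control by 0.04 ± 0.22 with a 95% confidence interval of -0.41 to 0.48, egr1 by 0.10 ± 0.12 (-0.14 to 0.35) and npas4a by 0.12 ± 0.33 (-0.54 to 0.77). These intervals measure the spread between fish and treat fish of 1 exposure replicate as independent. Over exposure replicates ier2a was 4.176 ± 0.255 in PFOS70 and 4.138 ± 0.632 in control (SD, n = 4). Of the 31 genes 18 had a higher mean, and the list did not pass camera (adjusted p = 0.55). Limma called 0 of 10231 genes, with or without the number as a block, and 564 had an unadjusted p under 0.05. The genes with the smallest p, none of which passed, included mccc1, an enzyme of leucine breakdown, at 0.23 ± 0.06, the tau kinase gene ttbk1a at 0.18 ± 0.05 and rpl22l1 at -0.34 ± 0.10.

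Ribosomal protein genes fell in PFOS70 by the preset test, 78 of 79 lower with a median of -0.18 (adjusted p = 2.86e-42; adjusted p = 0.406 with an estimated correlation). Examples are rpl5a at -0.29 ± 0.10 and rps27a at -0.20 ± 0.07, and none passed when adjusted over the list alone. With the mean of 4 fish as the unit, the exact two-sided permutation p of the list mean was 0.229 (n = 4), and 0.125 paired by number. In POP10 and POP70 the unpaired exact p was 0.486 and 0.257. With the 5 conditions permuted within numbers the list had a permutation p of 0.0977, or 0.846 adjusted over 26 lists. Genes of GABA and glutamate transmission rose by the preset test, 30 of 38 higher with a median of 0.13 (adjusted p = 0.018; adjusted p = 0.976 with an estimated correlation). Among them was the NMDA receptor subunit gene grin2aa at 0.24 ± 0.11. Both lists are among those that go with the composition component, and its mean was 0.15 ± 1.29 in PFOS70 against -0.34 ± 0.86 in control fish.

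**Figure D1:**
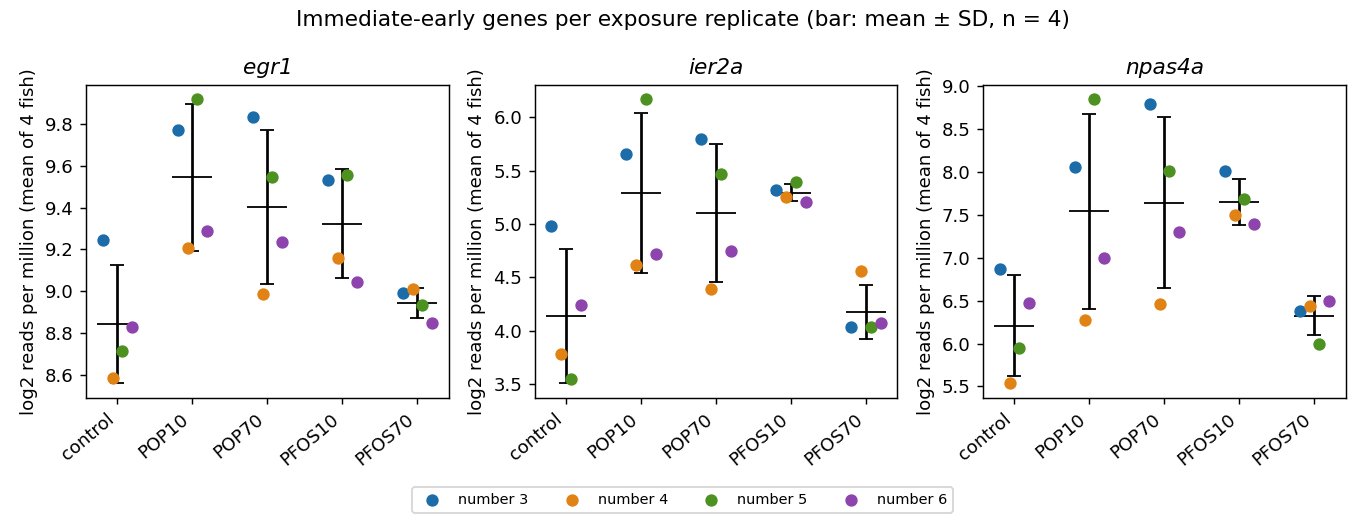
Levels of egr1, ier2a and npas4a in log2 RPM for each exposure replicate, where each point is the mean of 4 fish, each colour is a replicate number, and the bars give the mean ± SD of the 4 replicates. Replicates of POP10, POP70 and PFOS10 lie above the control replicate of the same number for all 3 genes, and the PFOS70 mean of ier2a is 4.18 beside 4.14 in control.

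**Figure D2:**
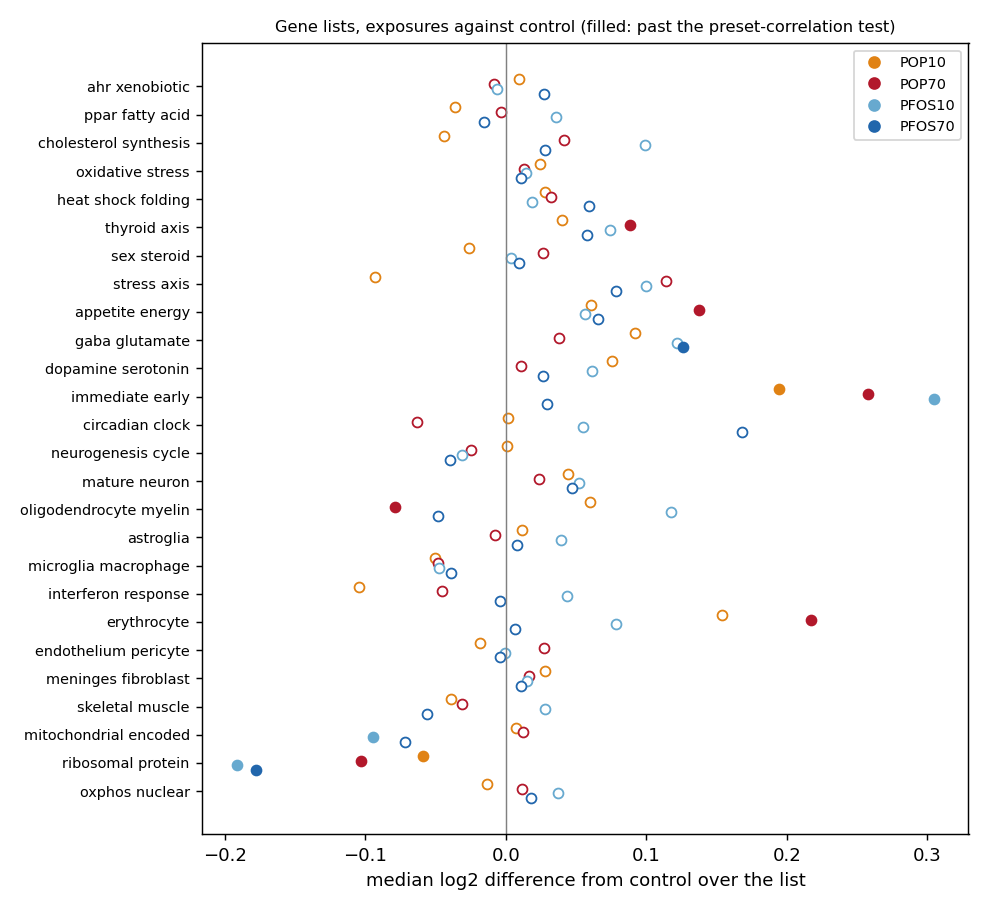
Median log2 difference from control over each of the 26 gene lists tested, 1 symbol per exposure, filled where camera with the preset correlation passed. Immediate-early genes lie highest in POP10 (0.19), POP70 (0.26) and PFOS10 (0.30), and ribosomal protein genes lowest in PFOS10 (-0.19) and PFOS70 (-0.18).

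A test of any difference among the 5 conditions called 7 genes (limma's F test), ier2a, ier2b, egr1, npas4a, zgc:122979, nr4a1 and egr4, and 390 had an unadjusted p under 0.05. Without number 3 it called 40 genes, without number 5 it called 0 and without number 6 it called 2. At the level of the exposure replicate, the mean of the immediate-early list was 5.64 ± 0.21 in control (SD, n = 4), 6.00 ± 0.33 in POP10, 6.02 ± 0.30 in POP70, 6.01 ± 0.14 in PFOS10 and 5.64 ± 0.04 in PFOS70. The exact two-sided permutation p against control was 0.114, 0.114, 0.0857 and 0.971, so at n = 4 none passed, although the list mean was higher in 4 of 4 numbers in POP10, POP70 and PFOS10. Paired by number, the exact permutation p was 0.125 in each of these 3 exposures, the smallest that 4 pairs can give.

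A panel of 30 genes named in advance gave little beyond the immediate-early members. Of these, cyp1a, cyp1b1, cpt1b, pgr, klf9, pomca and agrp were below the filter, and ahrra and cyp19a1b were not analysed here because no entry carried their names. Of the 21 genes tested, egr1, npas4a and fosab passed over the panel alone in POP10, egr1 and npas4a in POP70 and in PFOS10, and none in PFOS70. The glucocorticoid-induced gene fkbp5 was the lowest in POP10 at -0.78 ± 0.65, with a 95% confidence interval of -2.07 to 0.51. It lay above control in POP70, PFOS10 and PFOS70, at 0.66, 0.74 and 0.38. The myelin gene mbpa was the lowest in PFOS70 at -0.28 ± 0.14, and neither gene passed the threshold. The median SE over the panel was 0.17.

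The fold changes of the 4 exposures against control resembled each other across genes, with r from 0.515 for POP70 with PFOS70 to 0.799 for PFOS10 with PFOS70 and a mean of 0.622. Genes are not independent replicates, and the 4 comparisons share their 16 control fish. Unchanged groups were simulated by dealing the deviations of all fish from their group means, control fish included, over the 5 conditions within each sex. In each draw the 4 simulated exposures shared 1 simulated control group. The simulated mean r was 0.496, with an SD of 0.161 between 20 draws, so the observed mean lay within that spread. The mean covariance was 0.0179 beside 0.0113 in the simulation. Separate control fish for each exposure of a pair, by number, brought the mean r down to 0.0385. The control fish of a pair then came from different numbers, while the exposed fish came from all numbers. Differences between numbers thus enter the pair with opposite sign and push r down. With control and exposed fish both split by number, an alternative added after seeing the data, the mean r was 0.187. For the pair PFOS10 and PFOS70 the covariance was 0.0307, above the 20 draws that treat fish as independent, of which the highest was 0.0209. In draws of whole exposure replicates the mean covariance was 0.0115, and its highest value was not tabulated. By r these draws reached 0.843, above the observed 0.799, so by r this pair is not shown to exceed chance. By covariance this was not checked for whole exposure replicates. With separate control fish its correlation was 0.29.

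When each sex was tested alone, the calls lay in females exposed to POP10. There egr4 rose by 1.86 ± 0.36, 3.62-fold, from 5.83 ± 0.68 to 7.69 ± 1.37 (SD, n = 8), ier2a rose by 1.59 ± 0.31, from 3.81 ± 0.43 to 5.40 ± 1.01, and egr1 rose by 0.93 ± 0.17. The adjusted p was 0.00962 for egr4 and egr1 and 0.011 for ier2a (limma). These 3 genes had differences of 0.38, 0.72 and 0.48 in males, in the order egr4, ier2a and egr1. The male differences are made smaller by both control males of number 3, whose sex genes lie on the female side. Their egr1 was 9.470 and 9.827, beside 8.503 to 9.007 in the other control males. Their ier2a was 6.010 and 5.330, beside 3.305 to 4.807. None of the 4 interactions of exposure with sex called a gene, so the sexes are not shown to differ: 0 genes passed in limma, with 246, 205, 186 and 211 at an unadjusted p under 0.05 in POP10, POP70, PFOS10 and PFOS70. The interaction of egr4 in POP10 was 1.48 with an unadjusted p of 0.00472 (limma). It takes in the egr4 difference between the sexes in control fish. That difference went from -1.638 to -1.199 without both control males of number 3 and POP10 male fish 1 of that number.

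With the number as a block, POP10 females had 5 calls, npas4a and fosab besides those 3, and PFOS10 females had 2, ier2a and zgc:122979, where there were 0 without it. In the other exposures and sexes limma called 0 genes. The calls in POP10 females were lost without number 5 or number 6, each with 0 genes, and PFOS10 females had 7 without number 3. The counts at an unadjusted p under 0.05 were 333, 171, 488 and 285 in females of POP10, POP70, PFOS10 and PFOS70 and 369, 210, 329 and 447 in males.

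The mixture was set against PFOS alone at the matched PFOS content to ask what the rest of the mixture adds. At the low level the immediate-early genes stood at similar means, with differences between POP10 and PFOS10 of 0.22 for egr1 and -0.11 for npas4a. At the high level their means were higher with the mixture than with PFOS, by 0.46 for egr1, 0.93 for ier2a and 1.32 for npas4a, none past the threshold over all genes. Limma called 0 genes at either level, and 681 had an unadjusted p under 0.05 at the low and 423 at the high level. Without number 4 it called 3 genes at the high level. Without number 3 it called 1 gene at the low level and, at the high level, 756 genes between POP70 and PFOS70, 67 higher and 689 lower in POP70, with differences that opposed the composition component across genes (r = -0.71).

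Between the levels of PFOS, ier2a fell by 1.12 ± 0.22 from PFOS10 to PFOS70, from 5.30 ± 0.31 to 4.18 ± 0.32 (SD, n = 16), with an adjusted p of 0.0347 (limma). It was the only gene of 10231 that limma called, and 196 had an unadjusted p under 0.05. The gene npas4a stood at -1.33 and egr4 at -0.97 in the same comparison, below the threshold. The call was lost with the correlation between fish of 1 exposure replicate in the model, after quantile normalization and without the 4 PFOS70 fish of number 5, each with 0 genes, and also without number 3, 5 or 6. Over the 16 alternatives ier2a fell short of the threshold in 10 and kept the call in 6, while its difference stayed between -1.26 and -1.01. Between the levels of the mixture limma called 0 genes, with 385 at an unadjusted p under 0.05, and ier2a differed by -0.19.

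Transcripts of the circadian clock differed widely between the numbers. The clock repressor nr1d1 had a mean of 7.27 ± 0.53 in control fish of number 3 (SD, n = 4), 5.74 ± 0.30 in number 4, 3.52 ± 0.61 in number 5 and 7.72 ± 0.24 in number 6. The clock activator arntl1a went the other way, with 5.89 ± 0.22, 6.33 ± 0.17, 7.09 ± 0.04 and 5.91 ± 0.28. The 4 PFOS70 fish of number 5 stood apart from the other fish of their number: nr1d1 was 7.62 ± 0.27 in them and 3.36 ± 0.46 in the other 16, with the lowest of the 4 at 7.35 and the highest of the 16 at 4.42. The list of 34 clock genes passed in no exposure by camera with the preset correlation, with medians of 0.00, -0.06, 0.06 and 0.17 in POP10, POP70, PFOS10 and PFOS70.

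With the 4 PFOS70 fish of number 5 left out and the number as a block, a fit added after seeing the data, limma called 13 genes in PFOS70 against control, and 0 with those fish in it. Of these, 6 are in the clock list: ciarta stood at -0.97 ± 0.12, nr1d1 at -0.85 ± 0.14, per1b at -0.41 ± 0.07, bhlhe41 at -0.46 ± 0.08, dbpb at -0.44 ± 0.07 and nfil3-5 at 0.58 ± 0.10 (SE). In the same fit PFOS10 had 12 calls, with nfil3-5 at 0.61 ± 0.09 and ciarta at -0.58 ± 0.11 among them, so clock genes passed in both. These calls and their SE treat the fish of 1 exposure replicate as independent, and PFOS70 had 3 exposure replicates left. In the fit of all fish nr1d1 stood at 0.36, so its direction turned.

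**Figure D3:**
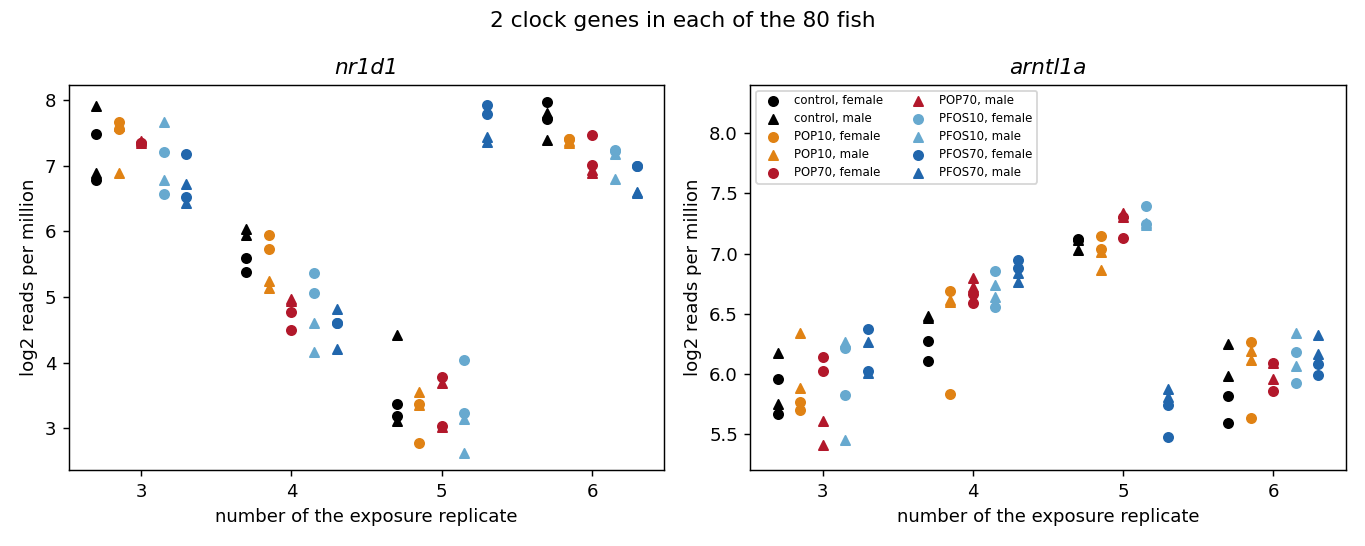
Levels of nr1d1 and arntl1a in log2 RPM in each of the 80 fish by the number of the exposure replicate, with colour for the condition and shape for the sex. The 4 PFOS70 fish of number 5 lie between 7.35 and 7.92 for nr1d1, where the other 16 fish of number 5 lie between 2.63 and 4.42.

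Over the 40 females and 40 males limma called 141 genes, 25 higher and 116 lower in females, and 1220 had an unadjusted p under 0.05. Without number 4 it called 25, without number 5 53 and without number 6 56. The lowest in females was dio2 (ENSDARG00000094857, chromosome 17 from 16873417 to 16876752), the deiodinase that makes active thyroid hormone within the brain, which fell by 1.85 ± 0.15, from 6.68 ± 0.92 in males to 4.83 ± 0.43 in females (SD, n = 40), with an adjusted p of 4.78e-15. Next were ca6, a secreted carbonic anhydrase, at -1.09 ± 0.11 and the haemoglobin gene hbba2 at -0.91 ± 0.24. Further genes lower in females were galn, the galanin precursor, at -0.83 ± 0.18, slc25a18, a mitochondrial glutamate carrier, at -0.80 ± 0.12, and hsd17b3, which makes testosterone from androstenedione, at -0.64 ± 0.08. Also lower were egr4, fosab, apof, tmprss4b, ssfa2 and the connexin gene cx47.1, between -0.78 and -0.56.

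Higher in females were sgk494a, a putative kinase, at 0.65 ± 0.12, gsg1l, an auxiliary subunit of glutamate receptors, at 0.58 ± 0.13, and the sterol synthesis enzymes msmo1 at 0.47 ± 0.10 and lss at 0.42 ± 0.09. SYNPR, atic, rbbp8, marcksa, kif26ab, rspo2, igf2bp3 and hhip followed, between 0.25 and 0.49.

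By camera with the preset correlation 14 of 26 lists passed between the sexes over all groups, by fry 6, or 11 with the number as a block, and by camera none with an estimated correlation, where the adjusted p was 0.0942 or more. Myelin genes were lower in females in 16 of 18, with a median of -0.30, and 13 passed when adjusted over the list alone, 6 over all genes, such as sox10 at -0.37 ± 0.07 and cldnk at -0.45 ± 0.10. Cholesterol synthesis was higher in 16 of 17, with a median of 0.13, and 5 passed over the list alone, 2 over all genes. Nuclear genes of oxidative phosphorylation were lower in 80 of 82, with a median of -0.12, and ribosomal protein genes higher in 76 of 79, with a median of 0.10. Immediate-early genes were lower in 27 of 31, with klf2a at -0.44 ± 0.07 and dusp1 at -0.52 ± 0.10 past the threshold over all genes. Further lists of cell types were lower in females, the erythrocyte genes in 13 of 15 (median -0.20, adjusted p = 0.00429), those of endothelium and pericytes in 16 of 21 (median -0.08, adjusted p = 0.00685) and those of microglia and macrophages in 12 of 16 (median -0.11, adjusted p = 0.0191). Neurogenesis and cell cycle genes were higher in 15 of 20 (median 0.05) and transcripts of the mitochondrial genome in 10 of 13 (median 0.04), and the xenobiotic response list was lower in 7 of 7 (median -0.12) and the fatty acid list in 25 of 30 (median -0.06). The median of the thyroid list was -0.14, and that of the astroglial list, with id1 at -0.35 ± 0.06, was -0.07.

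Among the 16 control fish alone limma called 0 genes between the sexes, and 154 had an unadjusted p under 0.05. With the number as a block it called 1, the immediate-early gene egr4, at -1.64 ± 0.32 (SE with the block) and an adjusted p of 0.0333, from 7.47 ± 0.91 in males to 5.83 ± 0.68 in females (SD, n = 8). Without number 3 it called 2. By the preset test 7 lists passed in control fish. Among them cholesterol synthesis was higher in 17 of 17 (median 0.26), erythrocyte genes lower in 14 of 15 (median -0.30) and immediate-early genes lower in 23 of 31 (median -0.19). Their adjusted p with an estimated correlation was 0.207 for cholesterol synthesis, 0.462 for the erythrocyte genes and 0.207 for the immediate-early genes. The immediate-early result and the egr4 call were lost without both control males of number 3, whose sex genes lie on the female side. Without the 3 such males, a fit added after seeing the data, the list median was -0.09 and the list did not pass the preset test (adjusted p = 0.0942). There egr4 stood at -1.20, and with the block at -1.31 with an adjusted p of 0.37 (limma). Most of its difference was thus kept, with fewer fish in the fit.

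The level of dio2 in males was 6.09 ± 1.38 in control (SD, n = 8), 6.40 ± 1.16 in POP10, 6.91 ± 0.65 in POP70, 6.98 ± 0.39 in PFOS10 and 7.02 ± 0.28 in PFOS70, against 4.68 to 4.91 in the females. The larger spread in the first 2 groups came from 3 males of number 3, both control males and POP10 male fish 1, at 4.42, 3.58 and 3.66, which were also on the female side for ca6 and hsd17b3. The lower means of these groups came from them too: without them control males averaged 6.79 ± 0.50 (n = 6) and POP10 males 6.79 ± 0.37 (n = 7). Without these 3 males, a fit added after seeing the data, limma called 426 genes between the sexes over all groups, 4 in POP10, 4 in POP70 and 3 in PFOS10.

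**Figure D4:**
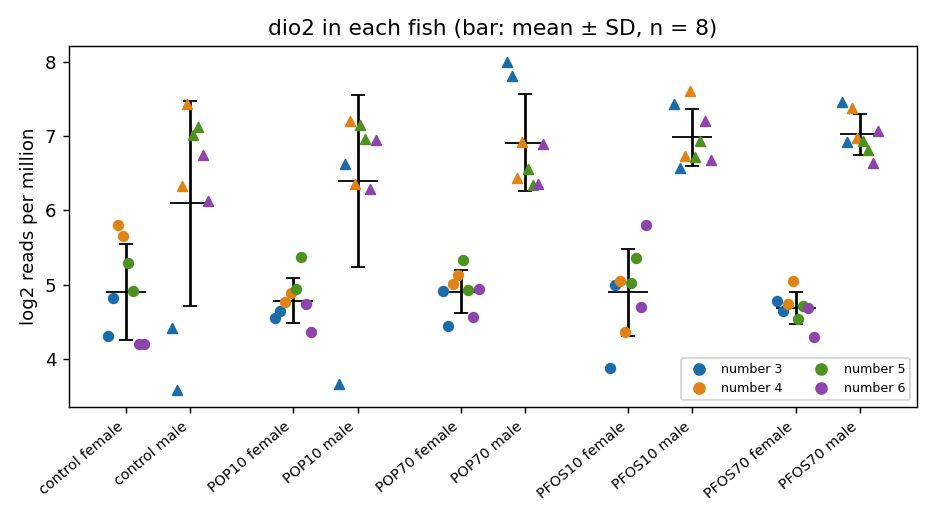
Level of dio2 in log2 RPM in each fish by condition and sex, with colour for the number of the exposure replicate and bars for the mean ± SD of 8 fish. Group means lie between 4.68 and 4.91 in females and between 6.09 and 7.02 in males, and 3 males of number 3 lie at 4.42, 3.58 and 3.66.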

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

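In this part the clock and composition covariates, the test of 12 exposure replicates against 4, the permutation within numbers, the test of time of day with its checks and the test of sampling order were chosen only after the result was seen, and the remaining tests after the pattern but before their own outcome was seen.

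Single fish or exposure replicates far from the others of their group were searched for in 150 groups of 4 or 8 values, and 8 were found where chance gives about 1 in 20 groups, or 7.5. By reads, POP70 male fish 1 of number 3 had 20.3 Mreads beside 10.1 to 14.3 in the other males of its group. By the composition component, control male fish 2 of number 3 lay at -2.66 beside -0.47 to 0.675, and the mean of POP10 number 3 at -0.677 beside 0.156 to 0.258. The level of egr4 was 6.6 in PFOS10 female fish 1 of number 3 beside 7.15 to 7.6. That of dio2 was 3.66 in POP10 male fish 1 of number 3 beside 6.29 to 7.2. The level of ca6 was 4.46 in control female fish 1 of number 3 beside 2.77 to 3.47, and 2.16 in POP70 female fish 2 of number 5 beside 2.74 to 3.19. The mean of ier2a in PFOS70 number 4 was 4.56 beside 4.03 to 4.07.

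Immediate-early genes were higher in POP10, POP70 and PFOS10 than in control, with a mean list median of 0.252. With the clock component as a covariate 105% of this median was left (0.264). This decides little about clock phase at sampling, since the component enters as 1 straight line and differs mostly between numbers. In control fish it went from -1.406 in number 5 to 1.051 in number 6. The differences of POP10, POP70 and PFOS10 from control were -0.13, -0.27 and -0.26. That of PFOS70, without its number 5 fish, was the largest at -0.44 (3 numbers). Its immediate-early list means in numbers 3, 4 and 6 were 5.595, 5.667 and 5.608, beside 5.920, 5.531 and 5.669 in control. The largest clock difference thus came with a higher list mean in number 4 only. RNA composition, as far as the composition component measures it, is argued against as the whole cause, since with this component as a covariate 92.9% was left (0.234). With either covariate the calls stayed 2, 0 and 1 in POP10, POP70 and PFOS10. Chance among the exposure replicates cannot be told apart: with the 5 conditions permuted within numbers the list mean had a permutation p of 0.00953, but 0.248 when adjusted over 26 lists. The 12 exposure replicates of these conditions lay above the 4 of PFOS70 (one-sided exact p = 0.00549), a grouping made after their means were seen, which decides nothing. An effect of the early exposure may remain as a hypothesis, beside clock phase at sampling, which is left open. Handling of the fish at sampling, which the labels do not give and which was not tested, stands beside them.

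The clock genes of the 4 PFOS70 fish of number 5 lay apart from the other fish of their number, with nr1d1 at 7.62 beside 3.36, and another time of day at sampling is a candidate explanation: across the 34 clock genes, which are not independent replicates, their shift correlated with the shift between numbers 5 and 3 with r = 0.966, and 30 of 34 had the same sign. With separate number 5 fish behind each shift r was 0.969 and 0.954, and with the number 5 fish of another condition in their place it was between -0.557 and 0.798, for shifts with an SD across genes of 0.217 to 0.257 beside 1.8. Whether the fish belong to another exposure replicate cannot be told apart, because 2 of the 4 fish were nearest to another number on 200 genes apart from the clock, and only 48.4% of 64 other fish, though 10 of 12 PFOS70 fish of other numbers, were nearest to their own. Without these fish the clock component differed between conditions within numbers (permutation p = 0.0278), nr1d1 differing from control by -0.16 ± 0.22 in POP10, -0.41 ± 0.47 in POP70, -0.50 ± 0.34 in PFOS10 and -0.89 ± 0.31 in PFOS70 (SD over 4, 4, 4 and 3 numbers). This fits an order of sampling within the day, and an effect of exposure on the clock stays open, as untested.

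The 3 males of number 3 with low dio2, both control males and POP10 male fish 1, lay on the female side for dio2, ca6 and hsd17b3 together, which no other fish of 80 did. A wrongly recorded sex may explain this: on 170 other genes that differ between the sexes 3 of 3 lay on the female side. The test is coarse, since 8 of 40 males and 4 of 40 females lay on the other side, and of the 7 other number 3 males only 5 lay on the male side; control male fish 1 scored 0.404, less than control male fish 2 of number 6 at 0.79, so the score does not single it out. RNA composition, as far as the composition component measures it, is argued against, because dio2 lay -6.54 SD of the other males from its level at that composition. A biological difference of these males stays open, as untested.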

How the results depend on the processing

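In this part the median-of-ratios scaling, the block together with the correlation, the covariates, the fits without the 4 PFOS70 fish of number 5 or without 3 males of number 3, and the split of control and exposed fish by number were chosen after seeing the data. Over the comparisons 348 of 445 alternatives stayed within 1.5 times the reported count or within the spread of the reported value and 97 moved. Over the named genes 2814 of 3036 kept direction and side of the threshold or stayed within the spread, 83 fell short of the threshold, 65 newly passed, 73 moved and 1 reversed. Where only samples or genes are left out the counts rest on fewer of these; otherwise the cause was not tested. All counts are limma's, and those at an unadjusted p under 0.05 stand with the results above. With the replicate block POP70 had 8, PFOS10 6, POP10 females 5, PFOS10 females 2 and female against male in control 1, and the block changed no other count by over 1.5 times. With the within-replicate correlation POP10 had 0, PFOS10 0, PFOS70 against PFOS10 0, any exposure 1, female against male in control 2 and in all groups 278. With block and correlation together POP70 had 2, female against male in control 2 and in all groups 247. With means of 4 fish and block POP10 had 0 and PFOS10 0. With library weights POP10 had 7 and PFOS10 6. With only control and that exposure in the fit POP10 had 0 and PFOS10 2. With quantile normalization PFOS10 had 0 and PFOS70 against PFOS10 0, and the latter had 0 with median-of-ratios scaling. With no filter PFOS70 against PFOS10 had 0 and any exposure 4. With the stricter filter POP70 had 4 and PFOS10 0. With voom POP10 had 1 and PFOS10 0. With the clock component as a covariate PFOS70 against PFOS10 had 0 genes and POP70 10 gene lists, and with the composition component PFOS70 had 4 gene lists. With an estimated correlation POP10 had 0 gene lists, POP70 1, PFOS10 0, PFOS70 0 and female against male in control 0. The mean r of the shared fold changes was 0.0385 with separate control fish and 0.187 with control and exposed fish split by number. Fewer fish and no shared controls enter in both, and in the first differences between numbers enter with opposite sign. Without the 4 PFOS70 fish of number 5 PFOS70 against PFOS10 had 0, PFOS70 females 1 and any exposure 3. With the block besides, POP70 had 10, PFOS10 12, PFOS70 13, PFOS10 females 4, PFOS70 females 7, POP70 males 1, PFOS10 males 2, PFOS70 males 6, POP10 against PFOS10 1, PFOS70 against PFOS10 0 and any exposure 24, and nr1d1 in PFOS70 reversed to -0.85. Without 3 males of number 3 POP10 had 4, POP70 4, PFOS10 3, female against male in control 1 and in all groups 426, with 7 gene lists in POP10 and 4 in PFOS70. With the block besides, POP10 had 6, POP70 5, PFOS10 3, POP10 females 5, PFOS10 females 1, and female against male 1 in control and 550 in all groups. Leaving out each number in turn gave these ranges. POP10 had 0 (without number 5) to 5 (without number 3), POP70 0 to 2 (without number 4), PFOS10 0 to 6 (without number 3), POP10 females 0 (without number 5 or 6) to 4, PFOS10 females 0 to 7 (without number 3) and PFOS70 females 0 to 1 (without number 5). POP10 against PFOS10 had 0 to 1 and POP70 against PFOS70 0 to 756, both highest without number 3, PFOS70 against PFOS10 0 to 1 (1 without number 4) and any exposure 0 (without number 5) to 40 (without number 3). Female against male had 0 to 2 (without number 3) in control and 25 (without number 4) to 173 in all groups. The gene lists had 3 to 4 (without number 6) in POP10, 3 to 6 (without number 6) in PFOS70 and 4 (without number 5) to 11 (without number 6) for female against male in control. A pseudocount of 10 was not run, because the values are not the log2 of x + 1. Depth limits single fish little: the smallest library had 71.2 reads for a gene at 10 RPM.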

Other observations

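In this part the exchanges of whole exposure replicates for POP10 females and for any exposure, and the exchange within numbers for any exposure, were chosen only after the result was seen.

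Fish were exchanged between the groups within each sex, 100 splits with the real one included, to ask whether chance can be excluded. This treats fish as independent, which fish of 1 exposure replicate are not, so it speaks to the spread between fish alone. Where the real count is 0 every split gives as many, so that such a count says nothing about chance. For PFOS10, 1 split of 100 gave as many genes as the real 1, with 0 the highest of the others, but 14 of 35 did with whole exposure replicates exchanged, so chance is not excluded. For POP10 it is not excluded either, with 5 of 100 (real 2, highest other 18). In POP70 and PFOS70, with a real count of 0 in limma, all 100 splits gave as many, with 188 and 1576 as the highest others. In females POP10 had 3 of 100 (real 3, highest other 72), but 5 of 35 with whole exposure replicates exchanged (real 3, highest other 288), so chance is not excluded there either, and POP70, PFOS10 and PFOS70 had 100 of 100 (real 0, highest others 75, 1 and 22). In males all 4 exposures had 100 of 100 (real 0, highest others 1299, 7, 4 and 1), as had the 4 interactions with sex (real 0, highest others 58, 1734, 0 and 1246). The counts at an unadjusted p under 0.05 stand with these results above. Splits that called many times the real count point to a structure of the samples, of which the composition component and the exposure replicate number are measured.

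Between the mixture and PFOS 100 of 100 splits gave as many at the low level (real 0, highest other 2) and at the high level (real 0, highest other 0), and 100 of 100 between the levels of the mixture (real 0, highest other 2). Between the levels of PFOS, 8 of 100 gave as many as the real 1, the ier2a call, with 2081 the highest other, so chance is not excluded. For any exposure 1 of 100 gave as many (real 7, highest other 3), but 61 of 100 did with whole exposure replicates exchanged (real 7, highest other 3359), and 30 of 100 with conditions exchanged within numbers and the number as a block (real 9, highest other 885), so chance is not excluded. For the sexes over all groups it is excluded, with 1 of 100 (real 141, highest other 5). In control fish 100 of 100 splits between the sexes gave as many genes (real 0, highest other 30) and 53 of 100 as many gene lists (real 7, highest other 12).

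With whole exposure replicates exchanged there were 35 splits per exposure. As many genes as in the real split came in 19 for POP10 (real 2, highest other 3650), 35 for POP70 (real 0, highest other 2478), 14 for PFOS10 (real 1, highest other 2527) and 35 for PFOS70 (real 0, highest other 3801). As many gene lists by the preset test came in 35 for POP10 (real 2, highest other 9), 21 for POP70 (real 6, highest other 14), 34 for PFOS10 (real 3, highest other 14) and 35 for PFOS70 (real 2, highest other 9). By this exchange, which ignores the shared numbers, chance is not excluded for the genes of POP10 and PFOS10 or for the gene lists of the 4 exposures. The real count of 0 genes in POP70 and PFOS70 leaves nothing to test, and the splits that called many times the real count point to a structure of the samples; which replicates they joined was not tabulated. With the conditions exchanged within numbers and the number as a block there are 8 splits, too few for a share under 0.05. As many genes came in 1 for POP10 (real 3, highest other 0), 1 for POP70 (real 8, highest other 0), 1 for PFOS10 (real 6, highest other 1) and 8 for PFOS70 (real 0, highest other 69).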
